A study of Mus musculus with 9 samples.

How the data were processed

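RNA was measured in 9 libraries of cardiomyocytes from CD-1 mice, 3 at postnatal day 1 (P1), 3 at P14 and 3 at P56. Per the labels' protocols, hearts were pooled for each sample, 12 at P1 and 6 to 7 at P14 and P56, and the design text calls the 3 libraries of an age a biological triplicate. The labels name the material as cardiomyocytes depleted of ribosomal RNA, and their protocols describe isolation of whole cells as well as sorting of nuclei that carry Pcm1. Which of these applied to each library is not settled by the labels, so the text speaks of libraries and transcripts.

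The unit analysed is the count: the authors deposited 1 table of integer counts per gene and library, with 15824 Ensembl genes. Per the submitters' processing notes, bcl2fastq 2.17.1.14, STAR 2.4.0g1 and featureCounts 1.4.2 were used with mouse genome build GRCm38. Whether counting took exons or whole genes, and whether it was stranded, is not given in the sources used here, so values of genes that overlap another gene or have close copies are uncertain. The smallest mean count of a gene in the table was 10 per library, a sign of an earlier removal of weakly counted genes. Gene names and coordinates were taken from the GRCm38 annotation, in which 15763 gene identifiers were found, 15758 of them with a GC content. The symbol Trmt44 occurred on more than 1 gene, and for any repeated symbol the gene with most counts was used.

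Totals were 49190887 to 58538025 counts per library at P1, 36619799 to 38878181 at P14 and 45866453 to 49535917 at P56. Counts were analysed with edgeR 4.0.16 in R 4.3.3. The filter filterByExpr removed 7 genes and left 15817, and library sizes were scaled by TMM. One fit (glmQLFit) held all 9 libraries with age as the only term, so the 3 ages share 1 estimate of the spread (common dispersion 0.0192, a biological coefficient of variation of 13.9%, prior degrees of freedom 3.68). Pairs of libraries of the same age differed more than counting error allows (chi-square per degree of freedom 5.45 to 99.8). Counting intervals and floors given below cover counting error only.

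The comparisons were P14 with P1, P56 with P14, P56 with P1, and the difference between the intervals (the change from P14 to P56 minus the change from P1 to P14), with an F test for any difference among the ages. All p-values for genes come from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over the 15817 genes, at a threshold of 0.05. Log2 changes are given as the fitted value ± its standard error (SE). Levels are CPM (computed from the counts with the TMM-scaled library sizes), given as mean ± SD of 3 libraries.

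The comparisons, tests, gene lists and naming rule were chosen before the data were examined. The rule for named genes took Pcm1, Myh6, Myh7, Tnni1, Tnni3, Mki67 and Top2a in every comparison. It added the 8 largest rises and the 8 largest falls among genes past the threshold with at least 10 CPM in the higher age, no overlap between the libraries compared and an established symbol. From each list it took up to 4 members per direction with the largest change past the threshold, and members given as not past it. Of the list members the rule allows, those whose calls changed in several settings were mostly left unnamed. A few genes that the rule selects are not reported here.

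The 33 gene lists comprised 31 written by symbol, with 526 of 579 symbols in the table, and 2 defined by a pattern of symbols (replication-dependent histones and cytosolic ribosomal proteins). Each list was tested with camera in limma 3.58.1 at the preset correlation of 0.01, with adjustment over the 33 lists, and again with a correlation estimated from the data and with fry, which tests whether the genes of a set move one way. Ranges of a list's adjusted p over the alternatives are those of camera and leave out fry. The camera test ranks a list against all other genes. The estimated correlation came from few libraries and rose to 0.954 in lists of other cell types. No list passed 0.05 with it, and the lowest adjusted p was 0.133 for P14 with P1, 0.294 for P56 with P14, 0.0975 for P56 with P1 and 0.665 for the difference between the intervals. Every list call below rests on the preset correlation, and the value with the estimated correlation is given beside it. Counts of list members refer to the adjustment over all genes, with counts adjusted over the list alone beside them where these differ.

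Lists of fibroblast, endothelial, leukocyte, epicardial, and smooth muscle and pericyte genes gave 59 measured markers of other cell types. Their mean log2 CPM per library is called the marker score. Abcc9 and Kcnj8, in the smooth muscle and pericyte list, are also expressed by cardiomyocytes. Cdkn1c, Myl4, Myl7, Nppa, Meg3, Mirg and Rian each stand in a pair of lists.

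Shares of all counts were compared among ages by an exact permutation test of the F statistic over every assignment of the 9 libraries to the ages, with adjustment over the 6 shares. The smallest p this test can give is 0.00357.

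Other settings chosen before the data were examined were RLE or upper-quartile scaling, DESeq2 1.42.0 or limma-voom in place of edgeR, no filter or 1 CPM in at least 3 libraries, scaling without mitochondrially encoded genes, haemoglobins and the 10 most abundant genes, only the libraries compared, a test against a log2 change of 1, and leaving out libraries. The marker score as a covariate and GC offsets per library were added after seeing the data. Upper-quartile scaling moved the median change of all genes from P1 to P56 from −0.03 to −0.14. Scripts in Python 3.11.15 with matplotlib 3.10.9 drew the figures.

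The steps were tested on simulated counts with known changes, drawn from the real means and library sizes with 15817 genes tested. For P14 against P1, 38.8% of 67 genes changed by 1.5-fold, 65.7% of 67 changed by 2-fold and 95.5% of 66 changed by 4-fold passed the threshold. For P56 against P14 these shares were 40.3%, 65.7% and 93.9%, and for P56 against P1 26.9%, 52.2% and 90.9%. Of the unchanged genes, 8, 5 and 12 passed in these comparisons. In the difference between the intervals a change at P14 counts in each interval, so genes changed by these folds at P14 had median fitted log2 differences of 1.13, 1.95 and 4.04, and 49.3%, 77.6% and 98.5% of them passed, with 4 unchanged genes past the threshold. In the simulation of P14 against P1, the only comparison in which lists were simulated, camera called the changed list and none of the other 32. Genes were drawn independently of each other, so these lists could not show whether the preset correlation passes too many lists. Few genes were changed in each simulation, so the adjustment was stricter there than in the real comparisons.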

Results

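Transcripts of the cardiomyocyte libraries separated the 3 ages. The first principal component of log2 CPM held 64.9% of the variance and ordered the libraries by age (P1 −92.8 to −88.5, P14 −10.6 to 18.8, P56 77.6 to 92.9), and the second held 25% and set P14 (−79.7 to −44.3) apart from the other ages (18.0 to 45.2). Of 15817 genes, 12336 (78%) differed among the ages at adjusted p under 0.05 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (n = 3 libraries per age). Pcm1, which encodes the centriolar satellite protein used to sort cardiomyocyte nuclei, stood at 248 ± 5.25 CPM at P1, 136 ± 9.90 at P14 and 173 ± 3.90 at P56. The marker score of other cell types was 1.29 to 1.85 at P1, 2.34 to 3.65 at P14 and 0.60 to 1.66 at P56. Markers of these cells are therefore given beside each group of genes. A sort on Pcm1 should remove nuclei of other cell types, and whether it was applied to each library is not settled here.

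From P1 to P14 the fetal troponin I transcript fell steeply and the adult myosin transcript rose. Tnni1, the slow skeletal troponin I of the fetal heart (ENSMUSG00000026418, chromosome 1 135779434 to 135810989), fell from 235 ± 8.19 to 1.29 ± 0.364 CPM, a log2 change of −7.50 ± 0.15 (adjusted p = 2.24e-09 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, n = 3 per age). Myh7, the β-myosin heavy chain of the fetal mouse ventricle (ENSMUSG00000053093), fell by 2.00 ± 0.20 (adjusted p = 2.89e-05), while Myh6, the adult α-myosin heavy chain (ENSMUSG00000040752), rose by 1.29 ± 0.21 (adjusted p = 0.000668). In the fit with the marker score Myh7 stood at −1.28, Myh6 at 2.03 and Tnni3 at 1.39, all called. Tnni3, adult cardiac troponin I, rose by 0.71 ± 0.20 (adjusted p = 0.0132), a call lost without replicate 2 of every age (0.63, adjusted p = 0.154, the highest over the alternatives, which start at 1.49e-05) and without replicate 3 (0.53, adjusted p = 0.105). Thrb, a thyroid hormone receptor (ENSMUSG00000021779, chromosome 14 17660261 to 18038090), rose from 68.4 ± 1.78 to 959 ± 99.5 CPM (3.81 ± 0.09). Mki67 and Top2a, transcripts of cycling cells, fell by 2.85 ± 0.31 and 2.73 ± 0.35. Pcm1 fell by 0.86 ± 0.06.

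The largest rises among genes of at least 10 CPM from P1 to P14 included metabolic enzymes and immune genes. Csdc2, an RNA-binding protein gene, rose by 6.27 ± 0.29, Alpl (tissue-nonspecific alkaline phosphatase) by 6.16 ± 0.25, and Nlrc5, the transactivator of MHC class I genes (ENSMUSG00000074151), by 6.03 ± 0.79. Pnpla3 (a lipid droplet hydrolase, 6.02 ± 0.30), Art1 (an ADP-ribosyltransferase, 5.70 ± 0.24), Xdh (xanthine dehydrogenase, 5.23 ± 0.54, or 3.40 with the marker score in the fit) and the interferon-inducible GTPase gene Iigp1 (136 ± 64.3 against 3.73 ± 0.299 CPM) followed. The largest falls after Tnni1 were those of Dcc, a netrin receptor (−6.87 ± 0.16), the olfactory receptor gene Olfr608 (29.0 ± 0.833 to 0.287 ± 0.101 CPM) and Grik3, a kainate receptor subunit (−6.23 ± 0.23). Igf2bp1, an RNA-binding protein of embryonic tissues (ENSMUSG00000013415, chromosome 11 95957163 to 96005940), fell by 6.20 ± 0.24. Cacng6, a calcium channel γ subunit, stood at −5.82 ± 0.33, Plppr1 at −5.51 ± 0.19 and Cdh3 (P-cadherin) at −4.78 ± 0.18. All had adjusted p of 0.000551 or below. Each of these rises exceeded the median rise of 1.90 among markers of other cell types, which follows from their choice as the largest rises and does not bear on their source.

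Between P1 and P14, 4493 of 15817 genes rose and 4350 fell by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 2111 and 1483 of them by a log2 change of at least 1. When the change was tested against a log2 of 1, 1206 genes rose and 840 fell. Without replicate 2 of every age, 2635 rose and 2514 fell. With the marker score in the fit, 1682 rose and 1994 fell by a log2 change of at least 1, which turns the balance of large changes.

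**Figure D1:**
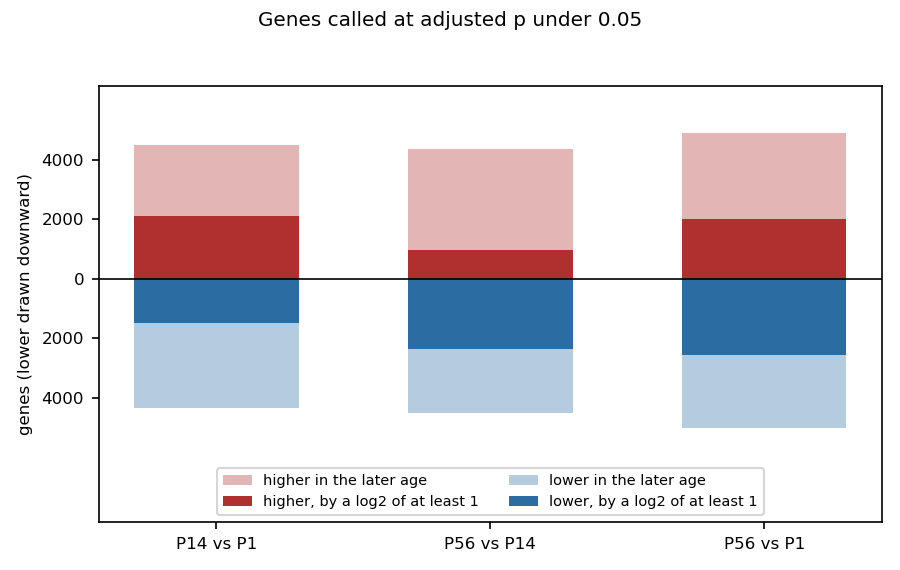
Bars give the number of genes (vertical axis, lower drawn downward) past adjusted p under 0.05 in each comparison of ages, with the darker part for a log2 change of at least 1. From P1 to P14 4493 genes were higher and 4350 lower, from P14 to P56 4356 and 4504, and from P1 to P56 4888 and 5016.

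Proliferation transcripts fell together. Of 30 mitosis genes, 28 fell and 1 rose from P1 to P14 (median log2 change −2.20, camera adjusted p = 2.89e-12, adjusted p = 0.333 with an estimated correlation). The spindle checkpoint kinase gene Bub1 fell by 3.22 ± 0.28 and the cytokinesis regulator Ect2 by 2.96 ± 0.21. The 1 rise was that of Cenpa, the centromeric histone H3 variant (0.78 ± 0.13, adjusted p = 0.000855, and 1.22 with the marker score in the fit). All 29 DNA replication genes fell (median −2.10, camera adjusted p = 1.56e-17, adjusted p = 0.133 with an estimated correlation), with Prim1 (DNA primase) at −3.17 ± 0.37, Rrm2 (ribonucleotide reductase) at −3.09 ± 0.32 (−4.65 with the marker score in the fit) and E2f1 at −2.83 ± 0.35. Of 34 replication-dependent histone genes, 30 fell and 0 rose by edgeR's test (31 fell when adjusted over the list alone; median −2.01, camera adjusted p = 2.2e-06, adjusted p = 0.333 with an estimated correlation), among them Hist1h2bb (−2.94 ± 0.39). Cell cycle inhibitors split, with 5 up and 6 down of 15 (camera adjusted p = 0.973). Cdkn1a (p21) rose by 2.06 ± 0.17 and Gadd45g by 1.44 ± 0.21, while Rbl1 (p107), which is itself made in cycling cells, fell by 2.88 ± 0.25 and Cdkn2c by 1.33 ± 0.26 (−2.295 in the fit with the marker score). Over the same interval 45 of 59 markers of other cell types rose and 5 fell (median 1.90), the opposite way to the mitosis and replication genes.

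Fetal growth genes also fell by P14. Of 25 D cyclin and growth pathway genes, 11 fell and 6 rose (13 and 6 when adjusted over the list alone; median −0.38, and −0.24 without P14 replicate 3; camera adjusted p = 0.00802, adjusted p = 0.133 with an estimated correlation). Igf2bp3 fell by 4.38 ± 0.18, Tead2 by 2.19 ± 0.28 and Lin28b, a repressor of let-7 microRNAs, by 2.00 ± 0.10, whereas Cyr61, Erbb3 and Wwtr1 (TAZ) rose by 1.01 ± 0.16, 0.89 ± 0.13 and 0.77 ± 0.05. Of 18 imprinted growth genes 13 fell and 0 rose by edgeR's test (14 fell when adjusted over the list alone; median −1.11, camera adjusted p = 1.59e-07, adjusted p = 0.133 with an estimated correlation), with Plagl1 at −2.94 ± 0.09, Mest at −2.32 ± 0.35 and Zim1 at −2.30 ± 0.14. The imprinted median was −2.37 with the marker score in the fit (8.08e-11), where Mest stood at −3.885. These lists moved down while markers of other cell types moved up (median 1.90).

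Contractile and channel genes took on more of the adult pattern by P14. Fetal sarcomere and stress genes ranked low as a list (camera adjusted p = 0.00117, adjusted p = 0.333 with an estimated correlation), with 6 down and 4 up of 16, a mean of −0.77 but a median of 0.10. That median was 0.03 without P1 replicate 2, and 0.16, −0.04 and 0.01 without P14 replicates 1, 2 and 3, 0.05 with GC offsets and −0.17 with the marker score in the fit. That score raised the medians of the adult sarcomere and channel lists below to 0.83 and 0.73. Cacna1h, a T-type calcium channel of the fetal ventricle, fell by 4.00 ± 0.13 and Tpm2 by 2.28 ± 0.27, while Acta1 (skeletal α-actin) rose by 1.71 ± 0.25 and Nppb by 0.82 ± 0.13 (0.52 with the marker score in the fit). Of 20 adult sarcomere genes, 11 rose and 0 fell by edgeR's test (median 0.47, camera adjusted p = 0.00803, adjusted p = 0.865 with an estimated correlation), among them Tcap (1.25 ± 0.16) and Myoz2 (1.13 ± 0.05). Of 23 calcium handling and ion channel genes, 13 rose and 3 fell (median 0.36, camera adjusted p = 0.0025, adjusted p = 0.753 with an estimated correlation). The potassium channel genes Kcnv2 (5 counts in all at P1) and Kcnd3 rose by 6.21 ± 0.38 and 4.72 ± 0.20, and the pacemaker channel gene Hcn2 by 3.11 ± 0.17. Slc8a1, the sodium-calcium exchanger, fell by 1.19 ± 0.08 and Gja1 (connexin 43) by 0.45 ± 0.06 (−0.28 with GC offsets). These rises run with that of the markers of other cell types (median 1.90), and the lists share no member with those markers.

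Energy metabolism lists did not pass the camera test from P1 to P14. Of 25 fatty acid oxidation genes 14 rose and 3 fell (4 fell when adjusted over the list alone; camera adjusted p = 0.221), with Ppara at 0.98 ± 0.16 and Ech1 at 0.84 ± 0.15 (1.55 and 1.27 with the marker score in the fit). Glycolysis genes split 9 up and 4 down of 20 (camera adjusted p = 0.511), with Hk2 up by 1.33 ± 0.17 and the fetal glucose transporter gene Slc2a1 down by 1.11 ± 0.13. In the TCA cycle 9 of 20 rose and 4 fell (5 fell when adjusted over the list alone; camera adjusted p = 0.289), with the mitochondrial pyruvate carrier gene Mpc1 up by 0.99 ± 0.11 and Ogdh by 0.81 ± 0.10. Of 31 nuclear-encoded respiratory chain genes 7 rose and 8 fell (camera adjusted p = 0.973, direction down, against a median of 0.04 and a mean of 0.01). Cox7a1, the heart and muscle form of a cytochrome oxidase subunit, rose by 0.78 ± 0.14 as the other form Cox7a2 fell by 0.57 ± 0.08. Mitochondrially encoded mRNAs had a median of −0.01 and a mean of 0.07, with 1 of 7 past the threshold upward and 0 by edgeR's test when adjusted over the list alone (camera adjusted p = 0.973, direction up). The rises in these lists were smaller than the median of 1.90 of markers of other cell types.

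Regulators of chromatin and transcription changed in the same interval. Of 25 DNA methylation and Polycomb genes, 14 fell and 5 rose (6 rose when adjusted over the list alone; median −0.22, camera adjusted p = 0.0106, adjusted p = 0.333 with an estimated correlation). Uhrf1 and Dnmt1, which copy DNA methylation after replication, fell by 2.24 ± 0.19 and 1.30 ± 0.09, and the Polycomb methyltransferase gene Ezh2 by 1.15 ± 0.08, while Dnmt3a, a de novo methyltransferase, rose by 0.83 ± 0.15 (1.29 with the marker score in the fit). Histone modifiers were 17 down and 8 up of 36 (camera adjusted p = 0.3), with Hmga2 at −3.01 ± 0.33 and Hdac7 at 1.29 ± 0.07. Cardiac transcription factors were 9 down and 3 up of 17 (median −0.24, camera adjusted p = 0.00138, adjusted p = 0.333 with an estimated correlation), with Hey2 at −3.43 ± 0.14, Tbx20 at −1.24 ± 0.08 and Irx4 at −1.05 ± 0.12. With the marker score in the fit adjusted p was 0.122 for each of these called lists, where the methylation median stayed at −0.24 and the transcription factor median went to −0.02 (range over the alternatives 0.00854 to 0.333 and 4.13e-05 to 0.333). The latter median was −0.42 with GC offsets. Nuclear receptors and maturation factors rose (11 up and 2 down of 19, 12 and 2 when adjusted over the list alone; median 0.57, 0.35 without P14 replicate 3 and 1.08 with the marker score in the fit; camera adjusted p = 1.44e-06, adjusted p = 0.133 with an estimated correlation). Rxrg rose by 3.76 ± 0.17 and Pparg by 2.97 ± 0.21, while Dio2, the enzyme that makes active thyroid hormone, fell by 1.97 ± 0.32. Clock genes did not pass the camera test (8 up and 2 down of 15, camera adjusted p = 0.221, but fry adjusted p = 0.0058), with Tef at 1.05 ± 0.11. Non-myocyte markers rose over this interval (median 1.90).

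Immune transcripts rose from P1 to P14. Of 20 interferon response genes, 18 rose and 1 fell (median 1.83, camera adjusted p = 0.000232, adjusted p = 0.408 with an estimated correlation), with Ifit1 (6 counts in all at P1) at 4.30 ± 0.44, the peptide transporter gene Tap1 at 4.17 ± 0.64 and Rsad2 at 3.52 ± 0.45, against Ifit2 at −0.94 ± 0.13. All 12 antigen presentation genes rose (median 3.43, camera adjusted p = 0.000274, adjusted p = 0.408 with an estimated correlation), including H2-D1 (3.87 ± 0.41) and Ciita, the MHC class II transactivator (3.86 ± 0.74, 9 counts at P1). Leukocyte markers rose beside them, 11 of 12 with 0 falling by edgeR's test (median 2.01, camera adjusted p = 0.0311, adjusted p = 0.785 with an estimated correlation). The leukocyte call was lost without P14 replicate 1 (median 1.56, adjusted p = 0.108), with GC offsets (1.95, 0.0587) and with the marker score in the fit (0.47, 0.661), in a range over the alternatives of 0.00346 to 0.785. The complement gene C1qa, at 0.144 ± 0.0259 CPM at P1, rose by 2.30 ± 0.43 and by 0.93 with the marker score in the fit (adjusted p = 0.147, alternatives from 8.12e-05).

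Markers of other cell types were higher at P14 than at P1. All 15 endothelial genes rose (median 2.12, camera adjusted p = 0.00105, adjusted p = 0.799 with an estimated correlation; median 0.34 and adjusted p = 0.17 with the marker score in the fit, alternatives from 1.87e-05), with Vwf at 3.01 ± 0.42 and the VEGF receptor gene Flt1 at 2.49 ± 0.37 (1.36 and 0.91 with the marker score in the fit). Fibroblast genes were 7 up and 1 down of 14 (median 1.33, camera adjusted p = 0.091), with Mfap5 at 2.83 ± 0.45 (0.81 with the marker score in the fit) and Fbln1 at 1.89 ± 0.10. Without P1 replicate 3 or P14 replicate 3 that list was called (median 1.57 and 1.71, adjusted p = 0.05 and 0.0036, in a range over the alternatives of 0.0036 to 0.865), and with the marker score in the fit its median turned to −0.95 (0.0235). Smooth muscle and pericyte genes were 7 up and 3 down of 11 (camera adjusted p = 0.371), with Myh11 at 2.36 ± 0.28. Epicardial genes were 5 up and 1 down of 7 (median 2.53, camera adjusted p = 0.221, and 2.82 with 0.0419 without P14 replicate 3, the lowest in a range up to 0.865), with the mesothelial mucin gene Muc16 at 3.03 ± 0.39 (1.74 with the marker score in the fit) and Tbx18 at −1.87 ± 0.24. The P14 libraries differ among themselves in this content, with marker scores of 2.34 to 3.65. Myh7, Tnni3, Thrb, Art1, Kcnd3 and Cacna1h overlap other annotated genes, and with the counting mode not given their values may include reads of those genes.

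**Figure D2:**
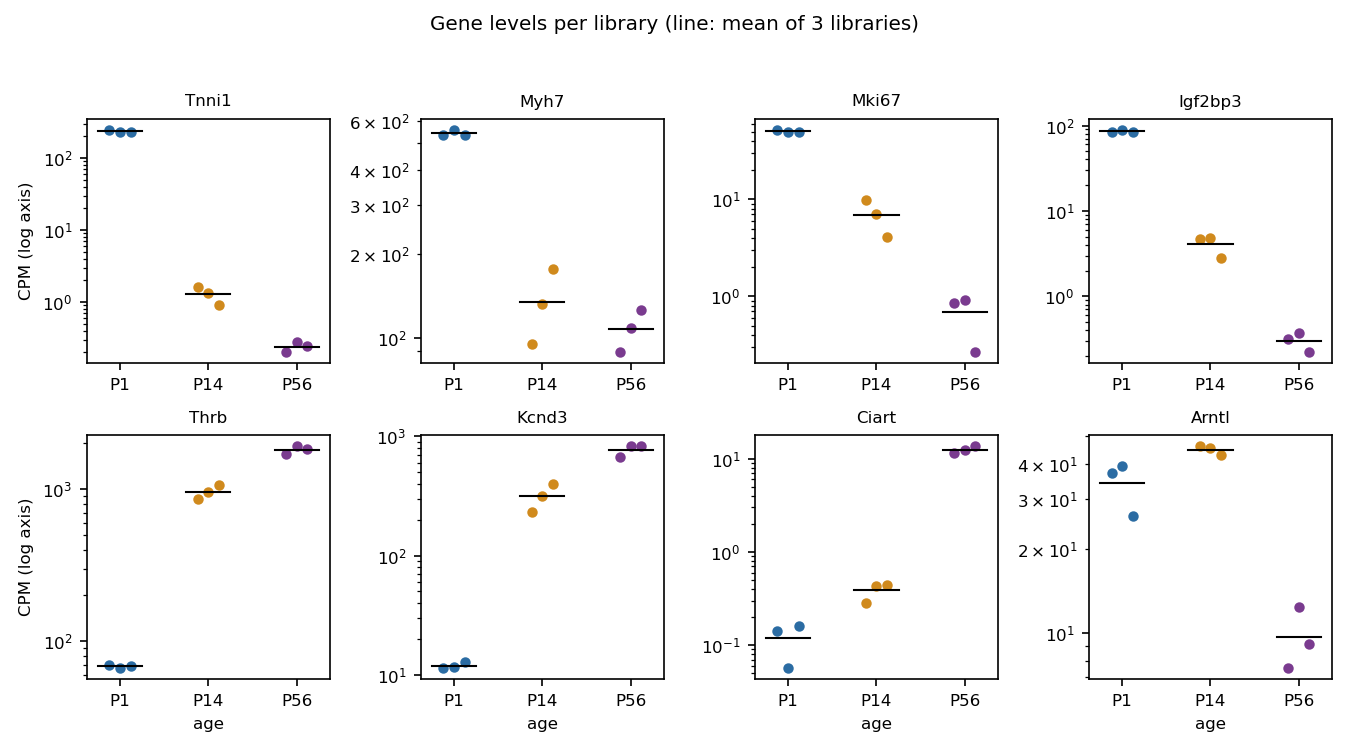
Points give the CPM of Tnni1, Myh7, Mki67, Igf2bp3, Thrb, Kcnd3, Ciart and Arntl in each library (log axis) at P1, P14 and P56, with a line at the mean of 3 libraries. Tnni1 fell from a mean of 235 CPM at P1 to 1.29 at P14, and Thrb rose from 68.4 to 959.

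From P14 to P56 the imprinted transcripts H19 and Igf2 fell and the transcript of a ketone body enzyme rose. H19 (ENSMUSG00000000031, chromosome 7 142575529 to 142578143), a noncoding RNA of fetal tissues, fell from 13.6 ± 6.69 to 0.220 ± 0.141 CPM (log2 change −5.94 ± 0.52, adjusted p = 1.8e-05 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, n = 3 per age), and its neighbour Igf2 (ENSMUSG00000048583), a fetal growth factor, by 5.66 ± 0.44 (adjusted p = 9.15e-06). Bdh1, mitochondrial 3-hydroxybutyrate dehydrogenase (ENSMUSG00000046598, chromosome 16 31422280 to 31458901), rose from 0.0352 ± 0.0137 CPM (4 counts in all) to 52.6 ± 11.1 CPM (10.42 ± 0.29). Mki67 fell by a further 3.35 ± 0.39 and Top2a by 3.26 ± 0.46, and Tnni1 by 2.41 ± 0.24. In the fit with the marker score H19 stood at −3.85, Igf2 at −3.76, Mki67 at −1.83 and Top2a at −1.76, all still called. Pcm1 rose by 0.34 ± 0.06 (adjusted p = 0.000967), and by 0.07 with GC offsets (adjusted p = 0.211, alternatives from 5.24e-06). Endothelial, fibroblast and other non-myocyte markers fell by a median of 2.15, with 42 of 59 down and 1 up.

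After P14 the adult myosin transcript fell by less than it had risen. Myh6 fell by 0.61 ± 0.21 (adjusted p = 0.0325), a call lost without P14 replicate 2 (−0.60, adjusted p = 0.077), P14 replicate 3 (−0.36, 0.108), P56 replicate 1 (−0.47, 0.105) or P56 replicate 2 (−0.67, 0.0532) and with GC offsets (−0.29, 0.202), in a range over the alternatives of 8.97e-05 to 0.202, and it stood at −1.65 with the marker score in the fit. Myh7 (−0.32 ± 0.20, adjusted p = 0.183) and Tnni3 (−0.33 ± 0.20, adjusted p = 0.182) did not pass. Without P14 replicate 1 Myh7 stood at −0.52 (adjusted p = 0.0109) and Tnni3 at −0.56 (0.00332), and with the marker score in the fit at −1.34 (7.13e-05) and −1.30 (0.000924), the alternatives reaching 0.962 and 0.847. Over this interval the 59 markers of other cell types fell by a median of 2.15.

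Other large rises from P14 to P56 were those of the clock repressor gene Ciart (ENSMUSG00000038550, 5.01 ± 0.23), the cadherin gene Cdh4 (4.59 ± 0.18), Prune2 (4.46 ± 0.24), the contactin gene Cntn5 (4.45 ± 0.13), the carboxylesterase gene Ces1d (4.06 ± 0.09) and the phosphodiesterase gene Pde11a (4.06 ± 0.28). The largest fall was that of Kcne1, a potassium channel β subunit (ENSMUSG00000039639, −6.02 ± 0.20). After H19 and Igf2 came Eln (elastin, −4.84 ± 0.47), Kcnn3 (a small-conductance potassium channel, −4.36 ± 0.55), Megf6 (−4.28 ± 0.38), Col1a1 (collagen I, −4.23 ± 0.60) and the imprinted noncoding RNA Meg3 (−4.04 ± 0.39). All had adjusted p of 0.000284 or below. In the fit with the marker score Eln stood at −2.60, Kcnn3 at −1.64, Megf6 at −2.45, Col1a1 at −1.02 and Meg3 at −2.16. Eln and Col1a1 are products of fibroblasts and smooth muscle, and the markers of other cell types fell beside them (median −2.15).

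Between P14 and P56, 4356 of 15817 genes rose and 4504 fell by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 979 and 2359 of them by a log2 change of at least 1. Against a log2 of 1, 472 rose and 1271 fell. With the marker score in the fit 2697 rose and 2599 fell, 992 and 1149 of them by a log2 change of at least 1. Without replicate 2 of every age 2585 rose and 2568 fell.

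Cell cycle transcripts fell again from P14 to P56. Of 30 mitosis genes 28 fell and 2 rose (median −2.15, camera adjusted p = 2.31e-08, adjusted p = 0.709 with an estimated correlation; median −1.27 and adjusted p = 0.00774 with the marker score in the fit). Aurora kinase B (Aurkb, 4 counts at P56) fell by 4.05 ± 0.56 and the midzone protein gene Prc1 by 3.64 ± 0.48, and they stood at −2.51 and −1.71 with the marker score in the fit. The rises were those of Cenpa (0.45 ± 0.13, adjusted p = 0.0152) and Cenpf (0.45 ± 0.11, adjusted p = 0.00557). Cenpa was 0.30 without P14 replicate 1, was not past the threshold without P56 replicate 3 (0.39, adjusted p = 0.0587) and stood at −0.16 with the marker score in the fit (0.49, alternatives from 0.00339). Cenpf stood at 0.29 with the marker score (0.33, alternatives from 0.000563) and at 0.24 with GC offsets (0.112). DNA replication genes were 15 down and 3 up of 29 (16 and 3 when adjusted over the list alone; median −0.62, camera adjusted p = 0.0275, adjusted p = 0.709 with an estimated correlation). That list was not called without P14 replicate 1 (median −0.46, adjusted p = 0.152) or with the marker score in the fit (−0.13, 0.842, alternatives from 0.0145). It was not called with the replicate number in the fit either (−0.612, 0.0531). Mcm5, part of the replicative helicase, fell by 2.04 ± 0.23 (−1.30 with the marker score in the fit), while Ccne1 rose by 1.70 ± 0.23 and Pole by 0.75 ± 0.14. The 59 markers of other cell types fell with the mitosis genes and by the same median, −2.15.

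Cell cycle inhibitors again split after P14. Cdkn1a fell by 3.59 ± 0.19 and Gadd45g by 2.02 ± 0.22, while Ccng1 rose by 0.83 ± 0.07 (0.54 with GC offsets) and Rbl2 (p130) by 0.53 ± 0.08, and the list had 7 down and 4 up of 15 (median −0.33, camera adjusted p = 0.128, and −0.66 with 0.0367 without P56 replicate 1, in a range over the alternatives of 0.0367 to 0.908). Replication-dependent histones were 10 down and 4 up of 34 (9 and 3 when adjusted over the list alone; median −0.46, or −0.25 with Hist1h3b, which had 0 counts at P56, at its bound; camera adjusted p = 0.58). Hist1h2be, 1 of many near-identical histone genes, rose by 1.39 ± 0.11. With the marker score in the fit the medians of the inhibitors and the histones turned to 0.215 (camera adjusted p = 0.908) and 0.365 (0.607). Non-myocyte markers had a median of −2.15.

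Growth genes and imprinted genes fell further. Of 18 imprinted genes 14 fell and 2 rose (median −2.47, or −2.03 with Dlk1, which had 0 counts at P56, at its bound; camera adjusted p = 1.97e-10, adjusted p = 0.294 with an estimated correlation). With the marker score in the fit the median was −0.92 (1.13e-09) and Mest stood at −2.12. Without it Mest fell by 4.13 ± 0.47 whereas Impact, a translation regulator gene, rose by 1.10 ± 0.06. Growth pathway genes were 14 down and 4 up of 25 (median −0.44, camera adjusted p = 0.0173, adjusted p = 0.294 with an estimated correlation; median −0.27 and adjusted p = 0.129 with the marker score in the fit, alternatives from 0.00362). Tead2 (−2.52 with the marker score in the fit) and Igf2bp3 fell by 3.81 ± 0.39 and 3.76 ± 0.25, while the YAP target Cyr61 rose by 1.76 ± 0.15 and Yap1 itself by 0.54 ± 0.06. The fall runs with that of the markers of other cell types (median −2.15), and these lists share no member with those markers.

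Contractile, channel and calcium genes diverged. Fetal sarcomere and stress genes were 6 down and 2 up of 16 (median −0.35, camera adjusted p = 0.0303, adjusted p = 0.709 with an estimated correlation), and the call was lost without P14 replicate 2 (−0.28, 0.0534) and with GC offsets (−0.135, 0.123), alternatives from 0.0221, while the median was −1.14 with the marker score in the fit (0.0391). The call was also lost with the replicate number in the fit (−0.345, 0.0531). Acta2 (smooth muscle α-actin) fell by 3.64 ± 0.19 and Cacna1h by 3.13 ± 0.17, while Acta1 rose by 1.73 ± 0.23 and Ankrd1 by 0.46 ± 0.09. Adult sarcomere genes were 4 up and 6 down of 20 (5 down when adjusted over the list alone; median −0.19, camera adjusted p = 0.671, and −0.865 with 2.63e-05 with the marker score in the fit, alternatives up to 0.994), with Tcap at 1.34 ± 0.16. Of 23 calcium handling and channel genes 10 rose and 5 fell (median 0.22, camera adjusted p = 0.0275, adjusted p = 0.709 with an estimated correlation). Without P14 replicate 1 the median was 0.07 and adjusted p 0.305, and with the marker score in the fit −0.41 and 0.701, alternatives from 0.00563. Kcnv2 (ENSMUSG00000047298) rose by 3.97 ± 0.20, the inward rectifier gene Kcnj2 by 1.30 ± 0.10 and phospholamban (Pln) by 1.23 ± 0.08, while Cacna1g fell by 2.24 ± 0.14 and Hcn2 by 1.19 ± 0.16. Hcn2 stood at −0.55 with GC offsets and −1.83 with the marker score in the fit. The non-myocyte markers, which include smooth muscle, fell by a median of 2.15.

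Among energy genes, TCA cycle transcripts rose after P14, 8 up and 1 down of 20 (median 0.15, camera adjusted p = 0.0275, adjusted p = 0.709 with an estimated correlation). That call was lost without P14 replicate 1 (0.12, 0.0737) or P56 replicate 2 (0.12, 0.0539), with the marker score in the fit (0.06, 0.78) and with GC offsets (0.05, 0.0693), alternatives from 0.00936. Mpc1 rose by 1.23 ± 0.11 (0.72 with the marker score in the fit) and Suclg2 by 0.89 ± 0.05. Glycolysis genes were 6 up and 2 down of 20 (median 0.18, camera adjusted p = 0.0818, with 0.15 and 0.0186 without P14 replicate 3, 0.19 and 0.0448 without P56 replicate 1, and 0.38 and 0.000282 with GC offsets, in a range up to 0.908), with the insulin-responsive glucose transporter gene Slc2a4 up by 1.49 ± 0.11, Slc2a1 by 1.50 ± 0.13, Ldhb up by 0.86 ± 0.07 and Pfkp down by 0.53 ± 0.07. Fatty acid oxidation genes split 6 up and 9 down of 25 (10 down when adjusted over the list alone; camera adjusted p = 0.686), with lipoprotein lipase (Lpl) up by 1.80 ± 0.08 and Etfa by 0.61 ± 0.06 against Pdk4, an inhibitor of pyruvate dehydrogenase, down by 3.25 ± 0.46 and Acadvl by 0.91 ± 0.12. Respiratory chain genes were 9 up and 3 down of 31 (camera adjusted p = 0.671), with Uqcrc2 at 0.36 ± 0.05 (0.17 with GC offsets). All 7 mitochondrially encoded mRNAs fell (median −0.83, camera adjusted p = 0.0244, adjusted p = 0.709 with an estimated correlation), among them mt-Nd5 (−1.23 ± 0.17). The call was lost without P14 replicate 1 (−0.77, 0.0737) and with the marker score (−0.21, 0.842, alternatives from 0.000206), where mt-Nd5 stood at −0.62 (0.0843, alternatives from 2.11e-11). These mRNAs fell as the non-myocyte markers did (median −2.15). Carried-over cytoplasm as a source was not tested.

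Clock genes of opposite phase parted between P14 and P56. Dbp, Tef and Per2 rose by 2.60 ± 0.13, 1.65 ± 0.11 and 1.32 ± 0.09, and the activators Arntl (Bmal1), Npas2 and Clock fell by 2.21 ± 0.19, 1.33 ± 0.08 and 0.67 ± 0.06. The list had 8 up and 4 down of 15 (9 and 4 when adjusted over the list alone; median 0.66, camera adjusted p = 0.00793, adjusted p = 0.709 with an estimated correlation; median 0.53 and adjusted p = 0.168 with the marker score in the fit, alternatives from 0.000224). The times of day of collection were not used here. Nuclear receptors split 7 up and 6 down of 19 (7 and 7 when adjusted over the list alone; camera adjusted p = 0.293). Pparg rose by 2.32 ± 0.19, the mineralocorticoid receptor gene Nr3c2 by 1.29 ± 0.07 and Thrb by 0.92 ± 0.08, while Thra fell by 1.24 ± 0.09 (−0.78 with GC offsets). Neither split follows the fall of the non-myocyte markers (median −2.15).

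Chromatin and transcription factor lists did not pass the camera test after P14. DNA methylation and Polycomb genes were 10 down and 2 up of 25 (camera adjusted p = 0.149, but fry adjusted p = 0.00198), with the Polycomb gene Pcgf2 at −1.82 ± 0.17. Histone modifiers split 11 up and 13 down of 36 (median −0.11, camera adjusted p = 0.556, and −0.17 with 0.0391 with the marker score in the fit, the lowest in a range up to 0.862), with Smarca2 at 0.94 ± 0.09 and Kmt2d at −1.21 ± 0.16 (−1.92 with the marker score in the fit, −0.80 with GC offsets). Cardiac transcription factors were 4 up and 5 down of 17 (median −0.04, mean −0.02, camera direction up, adjusted p = 0.849), with Mef2c at 0.98 ± 0.12 (1.50 with the marker score in the fit) and Zfpm2 at 0.55 ± 0.07 (0.35 with GC offsets). Cytosolic ribosomal protein genes fell, 35 down and 2 up of 81 (29 and 2 when adjusted over the list alone; median −0.34, camera adjusted p = 0.0188, adjusted p = 0.709 with an estimated correlation). The ribosomal call was lost without P14 replicate 1 (−0.31, 0.0737) and with the marker score in the fit (−0.01, 0.838, alternatives from 0.00662), and Rplp0 fell by 0.84 ± 0.17 but stood at −0.02 with that score (adjusted p = 0.957, alternatives from 4.6e-05). Rpl3l, the striated muscle paralog of Rpl3, rose by 0.97 ± 0.22 and stood at −0.0310 with it (0.936, alternatives from 7.52e-05). The ribosomal genes thus fell alongside the non-myocyte markers (median −2.15).

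Immune genes fell in part. Interferon response genes were 8 down and 1 up of 20 (camera adjusted p = 0.267), and antigen presentation genes 4 down and 0 up by edgeR's test of 12 (3 down when adjusted over the list alone; camera adjusted p = 0.459), with H2-Q4 at −2.26 ± 0.46 and H2-D1 at −1.80 ± 0.36. With the marker score in the fit H2-Q4 stood at −3.41 and H2-D1 at −1.59 (adjusted p = 0.0674, alternatives from 2.68e-06). Leukocyte markers were 1 down and 0 up by edgeR's test of 12 (0 down when adjusted over the list alone; median −0.58, camera adjusted p = 0.556, and 1.59 with 0.0178 with the marker score in the fit, in a range up to 0.883).

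Fibroblast and vascular transcripts fell from P14 to P56. Of 14 fibroblast genes 13 fell (14 when adjusted over the list alone; median −2.64, camera adjusted p = 0.000364, adjusted p = 0.709 with an estimated correlation), with Col3a1 at −3.90 ± 0.56 and fibronectin (Fn1) at −3.53 ± 0.50 (−0.83 and −0.72 with the marker score in the fit). All 15 endothelial genes fell (median −2.69, camera adjusted p = 4.7e-06, adjusted p = 0.709 with an estimated correlation), with Vwf at −3.13 ± 0.43 and Egfl7 at −3.11 ± 0.33 (−0.96 and −1.57 with the marker score in the fit). Epicardial genes fell (6 of 7, median −3.53, camera adjusted p = 0.00137, adjusted p = 0.709 with an estimated correlation), with Muc16 at −4.28 ± 0.44 (−2.56 with the marker score in the fit). With the marker score in the fit these 3 lists were not called (median −0.56, −0.45 and −1.61, adjusted p = 0.838, 0.0667 and 0.123, alternatives from 1.89e-07, 3.43e-09 and 4.12e-05), which follows from the score holding their genes. Smooth muscle and pericyte genes were 7 down and 1 up of 11 (median −1.27, camera adjusted p = 0.0784), with Mylk at −2.02 ± 0.26 (−0.78 with the marker score in the fit). That list was called without P14 replicate 3 (−1.62, 0.0349) and without P56 replicate 1 (−2.04, 0.00936, the lowest in a range up to 0.808). Its median turned to 0.209 with the marker score in the fit (0.808). Because the fall in these cell types runs with the fall in many other genes, changes of a similar size at P56 cannot be given to cardiomyocytes alone. Igf2, Pln, Tead2, Dbp, Bdh1, Ciart, Thra and Arntl are among the named genes that overlap other annotated genes, so their values carry that uncertainty.

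The potassium channel gene Kcnv2 was among the largest rises from P1 to P56. It rose from 0.0299 ± 0.0123 CPM (5 counts) to 36.9 ± 4.73 CPM, a log2 change of 10.18 ± 0.33 (adjusted p = 9.9e-09 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, n = 3 per age). Lgi1 (4 counts at P1) rose by 9.48 ± 0.46, the medium-chain acyl-CoA synthetase gene Acsm5 (6 counts) by 8.43 ± 0.44, Bdh1 by 8.21 ± 0.23, the galactosyltransferase gene B3galt2 by 7.41 ± 0.20 and Art1 by 7.19 ± 0.26. Igf2bp1 went from 3631 counts to 1, a ratio of 2810 per depth (counting interval 503 to 111000). Tnni1 fell by 9.91 ± 0.18, Olfr608 (5 counts at P56) by 9.49 ± 0.34, Plppr1 by 9.08 ± 0.24 and Igf2bp3 by 8.14 ± 0.24. Tgif2 and the prolyl hydroxylase gene P4ha3 (6 counts each at P56) fell by 8.08 ± 0.45 and 8.04 ± 0.31, and Cdh3 by 7.84 ± 0.24. Over the span the 59 markers of other cell types had a median of −0.44, with 11 up and 17 down.

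Over the same span Myh7 fell by 2.33 ± 0.20 (adjusted p = 5.28e-06) and Myh6 rose by 0.68 ± 0.21 (adjusted p = 0.0171). The Myh6 call was lost without P1 replicate 3 (0.65, adjusted p = 0.0559), P56 replicate 2 (0.62, 0.0555) or P56 replicate 3 (0.60, 0.0592), in a range over the alternatives of 0.000444 to 0.172, and Myh6 stood at 0.38 with the marker score in the fit. Tnni3 did not pass (0.37 ± 0.20, adjusted p = 0.129), and did with GC offsets (0.45, 0.0349) and without P14 replicate 1 (0.37, 0.0125), alternatives from 0.000289 to 0.492. Pcm1 fell by 0.52 ± 0.06. Of 15817 genes 4888 rose and 5016 fell, 2016 and 2562 of them by a log2 change of at least 1. Against a log2 of 1, 1342 rose and 1706 fell.

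Proliferation and growth genes fell between birth and P56. Mki67 and Top2a fell by 6.20 ± 0.39 and 5.99 ± 0.45. Of 30 mitosis genes 28 fell and 2 rose (median −4.49, camera adjusted p = 1.67e-16, adjusted p = 0.266 with an estimated correlation), with Bub1 at −6.67 ± 0.39 and Ttk at −6.08 ± 0.48 against Cenpa at 1.23 ± 0.13. All 29 DNA replication genes fell (median −2.61, camera adjusted p = 5.14e-15, adjusted p = 0.25 with an estimated correlation), with E2f1 (5 counts at P56) at −6.45 ± 0.50 and Mcm5 at −4.81 ± 0.21. Replication-dependent histones were 27 down and 2 up of 34 (median −2.30, camera adjusted p = 0.000191, adjusted p = 0.603 with an estimated correlation). Of 18 imprinted growth genes 17 fell and 1 rose (median −3.21, camera adjusted p = 5.14e-15, adjusted p = 0.0975 with an estimated correlation). H19 fell by 7.20 ± 0.52 and Igf2 by 6.70 ± 0.45, Dlk1 had 0 counts at P56 and was at least 74.6-fold lower than at P1, and Impact rose from 27.1 ± 1.31 to 59.8 ± 2.45 CPM. Growth pathway genes were 14 down and 7 up of 25 (16 and 7 when adjusted over the list alone; median −0.68, camera adjusted p = 0.000574, adjusted p = 0.0975 with an estimated correlation). Cell cycle inhibitors were 10 down and 4 up of 15 (5 up when adjusted over the list alone; camera adjusted p = 0.24). The non-myocyte markers had a median of −0.44, far from that of the mitosis, replication and imprinted genes.

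Calcium handling, channel and TCA cycle genes rose over the span, and fetal sarcomere genes fell. Of 23 calcium handling and channel genes 14 rose and 5 fell (15 and 5 when adjusted over the list alone; median 0.48, camera adjusted p = 0.000448, adjusted p = 0.603 with an estimated correlation), with the transient outward current genes Kcnd3 and Kcnd2 at 6.01 ± 0.21 and 2.81 ± 0.09 and Cacna1g at −2.29 ± 0.14. Fetal sarcomere and stress genes were 9 down and 5 up of 16 (median −1.42, camera adjusted p = 0.000305, adjusted p = 0.266 with an estimated correlation), with Cacna1h at −7.14 ± 0.16, Myl7 at −3.37 ± 0.51 and Acta1 at 3.44 ± 0.25. Adult sarcomere genes were 8 up and 3 down of 20 (2 down when adjusted over the list alone; camera adjusted p = 0.121), with Tcap at 2.59 ± 0.16. TCA cycle genes were 12 up and 0 down by edgeR's test of 20 (median 0.25, camera adjusted p = 0.0168, adjusted p = 0.749 with an estimated correlation), with Mpc1 at 2.22 ± 0.11 and Ogdh at 1.44 ± 0.11. Glycolysis genes were 9 up and 2 down of 20 (median 0.13, camera adjusted p = 0.0934, 0.13 with 0.0462 without P14 replicate 3 and 0.18 with 0.0324 with GC offsets, the lowest in a range up to 0.792), with Slc2a4 at 2.21 ± 0.12. Fatty acid oxidation genes split 8 up and 9 down of 25 (10 down when adjusted over the list alone; median −0.09, mean 0.05, camera adjusted p = 0.577), with Lpl at 2.34 ± 0.08. Respiratory chain genes were 10 up and 8 down of 31 (9 and 8 when adjusted over the list alone; camera adjusted p = 0.767), and all 7 mitochondrially encoded mRNAs fell as single genes (median −0.85, camera adjusted p = 0.127, and 0.0462 at the same median without P14 replicate 3, the lowest in a range up to 0.802), with mt-Nd5 at −1.27 ± 0.17. The median of the non-myocyte markers was −0.44.

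Regulators differed in direction over the span. Nuclear receptors and maturation factors were 12 up and 4 down of 19 (median 1.03, camera adjusted p = 4.91e-05, adjusted p = 0.238 with an estimated correlation), with Pparg at 5.28 ± 0.22, Thrb at 4.73 ± 0.10, Rxrg at 4.33 ± 0.18 and Thra at −1.19 ± 0.09. Clock genes were 10 up and 3 down of 15 (median 1.12, camera adjusted p = 0.00411, adjusted p = 0.38 with an estimated correlation), with Tef at 2.70 ± 0.11, Dbp at 2.45 ± 0.13 and Arntl at −1.81 ± 0.19. DNA methylation and Polycomb genes were 14 down and 3 up of 25 (median −0.50, camera adjusted p = 0.00389, adjusted p = 0.266 with an estimated correlation), with Uhrf1 at −3.43 ± 0.20, Dnmt1 at −2.25 ± 0.10 and Cbx7 at 0.99 ± 0.15. Cardiac transcription factors were 12 down and 2 up of 17 (median −0.42, camera adjusted p = 0.0272, adjusted p = 0.603 with an estimated correlation), with Hey2 at −3.03 ± 0.14 and Tbx5 at 0.57 ± 0.13. Histone modifiers were 19 down and 6 up of 36 (camera adjusted p = 0.206). Ribosomal protein genes were 60 down and 1 up of 81 (median −0.54, camera adjusted p = 0.00116, adjusted p = 0.702 with an estimated correlation), with Rplp0 at −1.65 ± 0.17 and Rpl8 at −1.51 ± 0.19 against Rpl3l at 5.65 ± 0.28. Markers of other cell types had a median of −0.44.

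Antigen presentation genes stayed above their level at birth, 10 up and 0 down by edgeR's test of 12 (median 2.44, camera adjusted p = 0.0358, adjusted p = 0.749 with an estimated correlation). The call was lost without P14 replicate 1 (2.44, 0.0639) and with GC offsets (2.49, 0.0501), alternatives from 0.0036. Cd74, the MHC class II invariant chain (9 counts at P1), rose by 4.45 ± 0.49. Interferon response genes were 13 up and 1 down of 20 (median 1.60, camera adjusted p = 0.0661, with 1.60 and 0.0468 without P14 replicate 2, and 1.82 and 0.00573 without P56 replicate 1, the lowest in a range up to 0.792), with Tap1 at 3.73 ± 0.64 and Ifit2 at −1.08 ± 0.13. Leukocyte markers were 9 up and 0 down by edgeR's test of 12 (median 1.34, camera adjusted p = 0.24, and 1.88 with 0.019 with the marker score in the fit, in a range up to 0.839), so more leukocyte RNA is a candidate source of part of this rise that a sort on Pcm1 should remove. Fibroblast genes were 7 down and 1 up of 14 (median −1.47, camera adjusted p = 0.24, and −0.80 with 0.026 with the marker score in the fit, in a range up to 0.899), with Fn1 at −3.81 ± 0.51, endothelial genes 3 down and 0 up by edgeR's test of 15 (0 down when adjusted over the list alone; median −0.58, camera adjusted p = 0.525), smooth muscle and pericyte genes 3 down and 1 up of 11 (camera adjusted p = 0.686), and epicardial genes 4 down and 0 up of 7 (5 down when adjusted over the list alone; camera adjusted p = 0.172). Levels near 0 at 1 of these ages make the largest changes depend on few counts.

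The difference between the intervals (the change from P14 to P56 minus the change from P1 to P14) separated lists that turned from those that went on. It passed for 3809 genes upward and 4107 downward of 15817 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 1538 and 2848 of them by a log2 of at least 1, and for 1576 and 1998 without replicate 2 of every age (2473 upward without replicate 3). DNA replication genes fell less in the later interval (18 up and 0 down of 29 by edgeR's test, 20 up when adjusted over the list alone; median 1.26, camera adjusted p = 9.88e-05, adjusted p = 0.665 with an estimated correlation). The replication-dependent histones did likewise (14 up and 0 down of 34, 12 up when adjusted over the list alone; median 1.38, camera adjusted p = 0.0351, adjusted p = 0.92 with an estimated correlation), a call lost without P14 replicate 3 (0.99, 0.112, alternatives from 0.00257). Mitosis genes showed no called difference in change per interval, the later interval being longer (3 up and 0 down of 30, 2 up when adjusted over the list alone; median −0.15, mean −0.09, camera direction up with adjusted p = 0.709), but with the marker score in the fit their difference was 1.95 (0.00263, the lowest in a range up to 0.935). Imprinted genes had a median difference of −1.13 (camera adjusted p = 0.419), which the marker score in the fit turned to 0.945 (0.539). That score moved the medians of the replication genes and the histones to 2.21 and 3.05, both still called. Markers of other cell types turned from a median of 1.90 to −2.15.

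Lists that rose to P14 and then stopped or turned had negative differences. Nuclear receptors had a median of −0.84, or −1.74 with the marker score in the fit and −0.56 with GC offsets (10 down and 3 up of 19, 10 and 6 when adjusted over the list alone; camera adjusted p = 0.00292, adjusted p = 0.665 with an estimated correlation), interferon response genes −2.70 (17 down and 1 up of 20; camera adjusted p = 0.000229) and antigen presentation genes −3.90 (11 down and 0 up of 12 by edgeR's test, 12 down when adjusted over the list alone; camera adjusted p = 0.000338), with adjusted p = 0.665 with an estimated correlation for both. Cardiac transcription factors, which fell early, had a median of 0.51 (8 up and 3 down of 17, 9 and 3 when adjusted over the list alone; camera adjusted p = 0.015, adjusted p = 0.665 with an estimated correlation; median −0.09 and adjusted p = 0.722 with the marker score in the fit, alternatives from 2.36e-05). Endothelial (median −4.79, or −0.791 with the marker score in the fit, camera adjusted p = 2.67e-09), fibroblast (−3.42, 9.88e-05) and epicardial genes (−5.33, 0.000472) had negative medians as well. Their adjusted p was 0.665, 0.895 and 0.665 with an estimated correlation, and with the marker score in the fit the epicardial call was lost (−1.98, 0.539, alternatives from 3.37e-06) and the fibroblast median turned to 0.86 (0.239, alternatives from 8.22e-10). The remaining lists did not pass, with camera adjusted p of 0.0517 for adult sarcomere and for smooth muscle and pericyte genes, 0.0525 for leukocyte genes, 0.14 for immediate early and heat shock genes, 0.169 for mitochondrially encoded mRNAs and at least 0.419 for the others.

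Some of these lists passed in other settings. Adult sarcomere genes (median −0.48) did without P1 replicate 1 (−0.53, 0.0431), P1 replicate 3 (−0.43, 0.0444), P14 replicate 1 (−0.78, 0.00038) or P56 replicate 3 (−0.59, 0.0265), with RLE scaling (−0.485, 0.0479) and with the marker score in the fit (−1.43, 8.53e-09, alternatives up to 0.935). Smooth muscle and pericyte genes (median −3.45) did without P1 replicate 1 (−3.50, 0.0488), P1 replicate 3 (−3.36, 0.0465), P14 replicate 3 (−3.63, 0.00985), P56 replicate 1 (−3.80, 0.00451) or P56 replicate 3 (−3.19, 0.0345), alternatives up to 0.92. Their median shrank to −0.049 (0.707) with the marker score in the fit, which holds these genes. Leukocyte genes (median −2.70) did without P1 replicate 3 (−2.75, 0.041), P14 replicate 3 (−3.33, 0.00582) or P56 replicate 1 (−2.97, 0.0394), alternatives up to 0.92. With the marker score in the fit, which holds their genes, the leukocyte median turned to 1.29 (0.412). Calcium handling and channel genes (median −0.46) passed without P14 replicate 1 (−0.83, 0.0063) and with the marker score in the fit (−1.46, 9.83e-06), and mitochondrially encoded mRNAs (−0.85) without P14 replicate 3 (−1.27, 0.00459) and with GC offsets (−1.47, 0.00164). With the marker score in the fit the mitochondrial median turned to 0.309 (0.539). Fatty acid oxidation genes (−0.29) passed without P56 replicate 1 (−0.40, 0.0198) and glycolysis genes (median 0.08, adjusted p = 0.522) with GC offsets (0.40, 0.0116). The alternatives of these 4 lists reached 0.935.

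**Figure D3:**
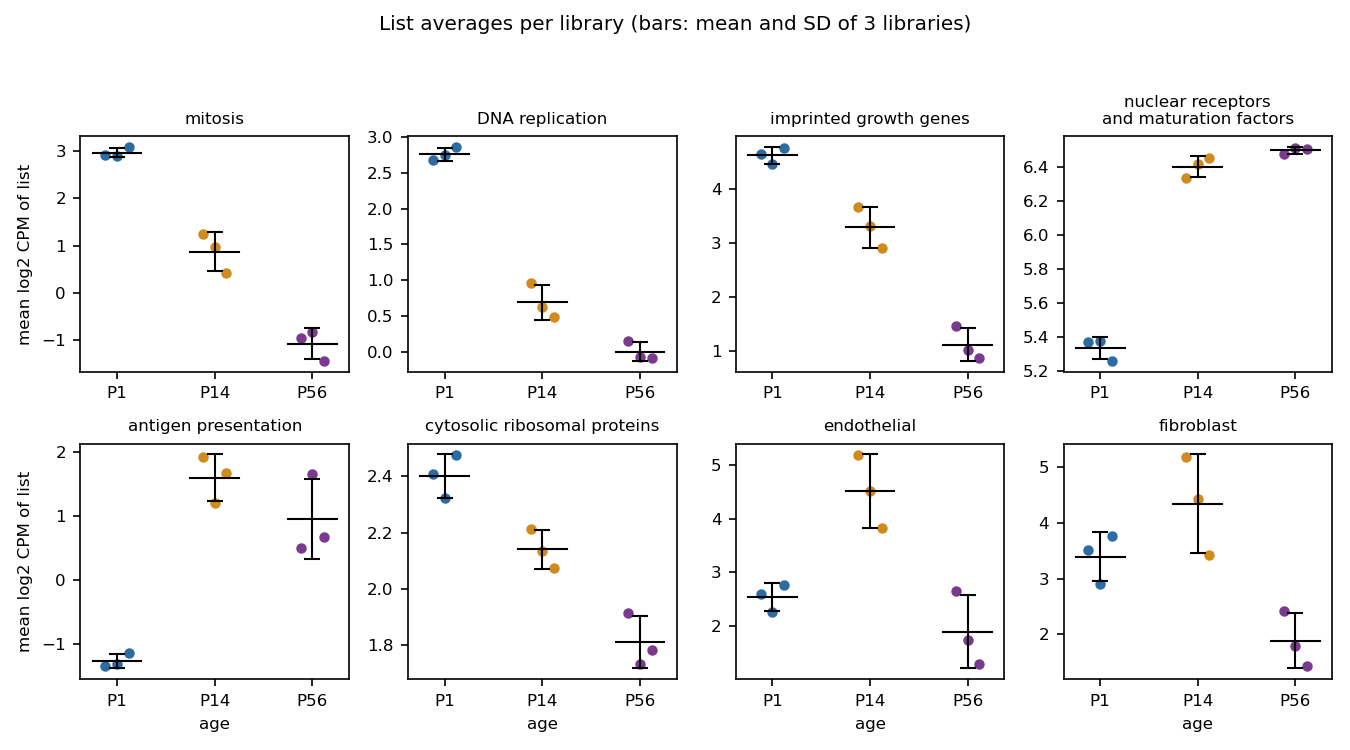
Points give the mean log2 CPM of a gene list in each library at P1, P14 and P56, with bars for the mean and SD of 3 libraries. Mitosis genes fell in each interval (median −2.20 and −2.15), whereas endothelial genes rose and then fell (2.12 and −2.69).

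In the overlap of calls, 1225 genes rose in each interval, 1133 fell in each, 1731 rose and then fell, and 1410 fell and then rose. Tnni1, Mki67, Top2a, Igf2bp3, Tead2, Cacna1h and Mest fell in each interval, Kcnv2, Thrb, Pparg, Tef, Tcap, Acta1, Mpc1 and Cyr61 rose in each, Cdkn1a, Gadd45g, Hcn2, H2-D1, Vwf and Muc16 rose and then fell, and Slc2a1 fell and then rose. Independent calls would overlap in 1237, 1239, 1279 and 1198 genes. The P14 libraries enter each interval with opposite sign, which pulls the changes apart. Across all genes 43.8% had the same sign in each interval, against 32.7% in simulated groups without change that share the P14 libraries, and the correlation was −0.03 against −0.52 (covariance −0.0402 against −0.0325, 20 simulations), with genes not independent replicates. With the marker score in the fit 548 rose and 416 fell in each interval, and with GC offsets 933 fell and then rose.

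Shares of counts within each library changed with age for the paired isoform genes. These are shares of raw counts, not corrected for gene length, and Tnni3, Myh6 and Myh7 overlap other annotated genes. Tnni3 itself did not pass from P1 to P56 (adjusted p = 0.129 by edgeR's test), so the troponin share moved mainly with Tnni1. Tnni1 made up 62.7 ± 0.729% of Tnni1 plus Tnni3 counts at P1, 0.637 ± 0.382% at P14 and 0.134 ± 0.0108% at P56 (adjusted exact p = 0.00714, n = 3 per age). Myh7 made up 17.2 ± 0.783%, 2.08 ± 0.0703% and 2.52 ± 0.158% of Myh6 plus Myh7 counts (adjusted exact p = 0.00714). Replication-dependent histones held 0.00670 ± 0.000979%, 0.00231 ± 0.000463% and 0.00301 ± 0.000145% of all counts (adjusted exact p = 0.00714). The share of mitochondrially encoded mRNAs was 0.116 ± 0.0112%, 0.108 ± 0.0329% and 0.0563 ± 0.0121% (adjusted exact p = 0.0857), that of haemoglobins 0.00130 ± 0.000197%, 0.00107 ± 0.000521% and 0.000735 ± 0.000208% (0.214), and that of the 10 most abundant genes 16.7 ± 0.303%, 19.1 ± 2.15% and 16.1 ± 1.38% (0.146). With the smallest possible p at 0.00357, the first 3 shares reached the strongest result that 9 libraries allow.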

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

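The marker score as a covariate and the GC offsets were chosen after the data were seen, and all other settings before. The number of genes that differed among the ages stayed between 8509 and 12711 when libraries were left out and between 10984 and 12475 under the other settings. Leaving out replicates or single libraries gave 2635 to 4662 genes higher and 2514 to 4577 lower at P14 than at P1, 2585 to 4435 and 2568 to 4551 at P56 than at P14, 3571 to 5195 and 3507 to 5361 at P56 than at P1, and 1576 to 3958 and 1998 to 4224 for the difference between the intervals. The lowest of these came from leaving out replicate 2 of every age, which removes 3 libraries, and no single library moved a count by over 1.5 times. Tested against a log2 change of 1, which asks for larger changes by construction, 1206 and 840, 472 and 1271, and 1342 and 1706 genes passed in the same order of comparisons. Adding the marker score to the fit left 2697 genes higher and 2599 lower at P56 than at P14, with 548 up and 416 down in each interval. Upper-quartile scaling gave 4098 genes higher and 6017 lower at P56 than at P1, and 4061 and 5022 at P14 than at P1. With GC offsets 933 genes fell and then rose. The cause was not tested.

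Several results changed direction with the marker score in the fit, and the cause was not tested beyond the score holding the fibroblast and leukocyte genes themselves. From P14 to P56 Cenpa stood at −0.16 (adjusted p = 0.49) and Rpl3l at −0.0310 (0.936), calcium handling and ion channel genes had a median of −0.41 (0.701) and leukocyte genes of 1.59 (0.0178). Fibroblast genes had a median of −0.95 from P1 to P14 (0.0235) and of 0.86 for the difference between the intervals (0.239). Medians of uncalled lists turned too, such as that of leukocyte genes for the difference between the intervals (1.29, 0.412). With fry 107 list results were the same and 25 gained a call. From P1 to P56 these included interferon response (fry adjusted p = 0.0034), cell cycle inhibitor (0.00668) and glycolysis genes (0.0032). From P14 to P56 they included cell cycle inhibitor and glycolysis genes (fry adjusted p = 0.0155 for each). Under all settings together, list results were the same in 1952 cases, lost their call in 82, gained it in 74 and reversed in 4, and the genes chosen for the text in 6011, 39, 10 and 2, a choice that left out most genes whose calls changed in several settings. Among results of these genes that kept their call, the log2 change moved by over 1.5 times in 46 with the marker score and in 9 with GC offsets. Of the shares, 21 values stayed within the spread between replicates. The difference between the highest and the lowest age mean was 0.004385 percentage points for the histone share, 0.003592 without replicate 3, and 15.12 for the Myh7 share, 15.61 without replicate 1.

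The deviations of libraries with the same replicate number correlated from −0.219 to 0.493, which shows no steady pairing by number. Between P14 and P56, however, they correlated at 0.493, 0.00773 and 0.364, against −0.479 to 0.222 for libraries with different numbers. A pairing of these ages is therefore not excluded. With the replicate block in the fit 4524 genes were higher and 4300 lower at P14 than at P1, 4299 and 4548 at P56 than at P14, 4879 and 5119 at P56 than at P1, 3727 and 4130 for the difference between the intervals, and 12223 differed among the ages. The block left 126 of the list results the same. It ended the calls of DNA replication and of fetal sarcomere genes from P14 to P56 (both 0.0531) and added those of ribosomal proteins from P1 to P14 (0.0436), smooth muscle and pericyte genes from P14 to P56 (0.0237) and, for the difference between the intervals, leukocyte (0.0317) and smooth muscle and pericyte genes (0.00557). Depth of 36619799 to 58538025 counts limits the genes near 0 counts at an age, whose changes rest on few reads.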

Other observations

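The test of other cell types for the first mitotic fall and the test of time of day were written after their values were seen, and the other tests below before. Atrial myocyte genes did not pass the camera test as a list, and its members past the threshold all fell. Fry called the list from P14 to P56 (fry adjusted p = 0.0227) and from P1 to P56 (0.00248). Of 8 such genes 3 fell and 0 rose by edgeR's test from P1 to P14 (1 fell when adjusted over the list alone; camera adjusted p = 0.447), 5 fell and 0 rose from P14 to P56 (median −1.41, camera adjusted p = 0.116) and 5 fell and 0 rose from P1 to P56 (median −1.76, camera adjusted p = 0.0942). The list was called without P14 replicate 3 from P14 to P56 (−1.47, 0.0263, the lowest in a range up to 0.838) and without P14 replicate 2 or 3 from P1 to P56 (0.038 and 0.0451 at the same median, alternatives up to 0.749). Gja5 (connexin 40) fell by 1.82 ± 0.24 from P1 to P14 and Dkk3 by 2.89 ± 0.38 from P14 to P56 (−1.01 with the marker score in the fit). Bmp10, an atrial growth factor gene, had 0 counts at P56 and was at least 29.1-fold lower than at P1. Over the intervals the non-myocyte markers had medians of 1.90 and −2.15.

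Immediate early and heat shock genes moved in opposing directions from P1 to P14, with 7 up and 6 down of 18 (median 0.12, mean −0.21, camera direction up with adjusted p = 0.404). Dusp1 and Fosl2 rose by 1.81 ± 0.15 and 1.49 ± 0.12 while the heat shock gene Hsph1 fell by 2.31 ± 0.42. From P14 to P56 they were 8 down and 2 up (camera adjusted p = 0.168), with Myc at −2.32 ± 0.31 and Jund at −1.53 ± 0.21 (−0.90 with GC offsets), and from P1 to P56 7 down and 4 up (camera adjusted p = 0.767). Nuclear-retained RNAs were 3 up and 3 down of 9 from P1 to P14 (3 and 4 when adjusted over the list alone; camera adjusted p = 0.662), with Neat1, the scaffold of paraspeckles, up by 2.77 ± 0.20. They were 3 up and 3 down from P14 to P56 (camera adjusted p = 0.556) and 3 up and 4 down from P1 to P56 (median 0.04, mean −0.49, camera direction down with adjusted p = 0.917). Ribosomal protein genes were 29 down and 1 up of 81 from P1 to P14 (24 and 1 when adjusted over the list alone; median −0.29, camera adjusted p = 0.061), with Rps26 down from 3.42 ± 0.304 to 1.70 ± 0.385 CPM and Rpl3l up by 4.68 ± 0.28. That list was called without P1 replicate 2 (−0.32, 0.0248), with GC offsets (−0.29, 0.0324) and with the marker score in the fit (−0.45, 0.00655, the lowest in a range up to 0.865). Schwann and neural genes (4 measured) were 1 up and 1 down, 0 up and 2 down, and 1 up and 2 down by edgeR's test in the comparisons of P14 with P1, P56 with P14 and P56 with P1 (2 and 1 in the first when adjusted over the list alone; camera adjusted p = 0.935, 0.459 and 0.722). Erythroid genes (4 measured) were 1 up, none past the threshold, and 1 down, with 0 by edgeR's test when adjusted over the list alone (camera adjusted p = 0.973, 0.58 and 0.753; median −0.06 and mean 0.19 in the first, with camera direction up). The only measured adipocyte gene gave camera adjusted p of 0.973, 0.7 and 0.765.

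The fall in mitotic transcripts was weighed against other sources. If fewer nuclei of other cell types caused the fall from P1 to P14, their markers should fall, and they rose by a median of 1.9, which speaks against that source. With GC offsets the upper 95% bound of the mean change of the 30 genes was −1.4 for P1 to P14 and −1.4 for P14 to P56, so GC content does not account for either fall. From P14 to P56 the mean was −1.94 (95% interval −2.57 to −1.32) without and −0.953 (−1.76 to −0.145) with the marker score in the fit. The score did not overlap between these ages, so the fit cannot tell how much of this fall came from other cell types. A sort on Pcm1 should remove those.

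The rise of 27 MHC class I and interferon genes from P1 to P14 had a mean of 2.25 (95% interval 1.59 to 2.90). Its lower bound was 1.57 with GC offsets, so GC content does not account for a rise of this size. With the marker score in the fit the bound was 1.16, above the 1 set beforehand. That score did not overlap between P1 (1.29 to 1.85) and P14 (2.34 to 3.65). The fit thus carried a slope from within ages across the gap, and it cannot exclude non-myocyte content as a source. With the leukocyte score in the fit the mean was 2.30 (0.79 to 3.81), and the lower bound of 0.79 lies under the 1 set beforehand. More leukocyte RNA at P14 could thus be part of the rise, and these libraries leave that open.

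The gap between clock genes of opposite phase widened by 2.88 (95% interval 2.49 to 3.26, 12 genes) from P14 to P56. The lower bound was 1.78 with the marker score in the fit. That score did not overlap between P14 (2.34 to 3.65) and P56 (0.60 to 1.66), so the fit cannot exclude a change in other cell types as a source. A different time of day of collection predicts the same gap of 2.88 as maturation of the clock, so the data may reflect either, and they do not separate them.

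When the 9 libraries were split into groups of 3 in 100 ways, 1 split called as many genes as the ages, the ages themselves, with 12336 genes against 4509 in the highest other split. For the difference between the intervals 1 of 100 splits, again the real one, called as many (7916, highest other 6036). Splits that keep the age groups but put P1 or P56 in the middle were not tried. The result thus bears on the grouping and not on P14 as the age of the turn. With the 6 libraries of a pair of ages alone, 1 of 10 splits called as many for P14 against P1 (8513, highest other 0), for P56 against P14 (7625, highest other 0) and for P56 against P1 (10517, highest other 0). With 10 splits a share under 0.05 is out of reach.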
